A study of Homo sapiens with 6 samples.

How the data were processed

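Gene expression was measured on 6 arrays in AGS, a human gastric adenocarcinoma cell line. Per the labels' protocols, cells received either an oligonucleotide inhibitor of the microRNA miR-25-3p or a non-targeting control RNA by lipid transfection, and the transfection was repeated after 24 h. Total RNA was taken 48 h after the first transfection, and 500 ng per sample was converted to biotin-labelled single-stranded cDNA fragments for hybridization to the Affymetrix Human Gene 1.0 ST array. The labels call the 3 samples of each group biological replicates.

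The deposited table holds log2 expression values for 257430 probe sets in each of the 6 arrays, 1 column per array, rounded to 2 decimals. The submitters' processing notes name RMA, Affymetrix Expression Console and Transcriptome Analysis Console, without versions or settings. The table is at the level of exon-sized probe sets, each read by few probes, so 1 probe set is noisier than a summary over a whole transcript. RMA forces arrays to nearly the same distribution, so a change shared by most genes would not be visible. The column medians lay between 6.02 and 6.07 and the values between 0.46 and 13.67. Scanner files and scan dates were not used here, and the number of arrays limits the precision.

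Probe sets were named from the platform annotation. A single gene symbol was given for 224320 probe sets, several for 10159, and the other 22951 were unnamed here. Of the 18701 symbols, 16068 were current in the RefSeq table of assembly GRCh38.p14, 2533 were updated through an unambiguous synonym and 100 were kept as given. The value of a gene on an array was the mean of the log2 values of the probe sets naming that gene alone, with a median of 10 probe sets per gene, 1045 genes with 1 probe set and at most 319. This gave 18656 genes, and dim genes were not filtered out. Genes or probe sets absent from the annotation given were not analysed here. The platform annotation gives no genome build here, so no coordinates are printed.

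The inhibitor group was compared with the control group in limma 3.58.1 (R 4.3.3) with lmFit and eBayes, without a replicate block, and Benjamini-Hochberg adjustment over all genes. The threshold was an adjusted p of 0.05. All fold changes are inhibitor minus control on the log2 scale, and each has its moderated standard error (SE). Gene lists were tested with limma's camera, which asks whether the genes of a list move apart from all other genes, with a preset inter-gene correlation of 0.01 and adjustment over 34 lists. Camera with an estimated correlation and fry, which tests for a shift in 1 direction or for change in either direction, were run beside it. The planned test of seed sites in 3′ untranslated regions needs transcript sequences, which were not used here, and it was not run.

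The design, the alternatives, the 34 gene lists and the rule for named genes were fixed before the data were examined. The lists were written from general knowledge of each pathway, and the list of reported targets of the miR-25/92 family was not checked for activity in AGS cells. The rule named the 8 genes with the largest rise and the 8 with the largest fall among called genes whose groups of arrays did not overlap or, with fewer than 5 calls in a direction, the 5 with the smallest p in that direction. It also named up to 2 positive and 2 negative members with the smallest p of every list described in detail, up to 4 each way for the reported targets, and MCM7.

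The fit was tested on simulated arrays drawn with the means of the 18656 genes and variances from the distribution fitted by eBayes, with 200 genes changed. Over 20 simulations, 0.6% of genes changed by 0.3 on the log2 scale were recovered at the threshold, 19.7% of those changed by 0.5, 90.8% of those changed by 1 and 99.5% of those changed by 2, with 5.7% false calls. Genes were drawn independently, which real genes are not.

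Alternatives covered the replicate block, leaving out each array, 2 further normalizations between arrays, 2 filters on dim genes, 3 other ways of combining probe sets, 3 other variance estimates, other thresholds and other list tests. Array weights and a restriction to probe sets whose identifier lay within 500 of the gene's median identifier were added after seeing the data.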

Results

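Messenger RNA was profiled in AGS cells, an established gastric adenocarcinoma line, after transfection of an inhibitor of miR-25-3p (3 arrays) or of a non-targeting control RNA (3 arrays). The comparison asked which transcripts differ when cells receive this inhibitor. MicroRNAs lower many of the messages they bind, so reported targets were among the lists examined. The mature microRNA itself was not measured. Its host gene, MCM7, carries miR-25 in an intron and does not report on an inhibitor of the mature form. MCM7 was at 8.42 ± 0.15 (SD, n = 3) in control arrays and 8.49 ± 0.087 (SD, n = 3) in inhibitor arrays on the log2 scale, a difference of 0.071 (SE 0.10) whose sign turned with the median or the brightest of its probe sets.

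Genes of mitosis were slightly higher as a group in the inhibitor arrays, and genes of glycolysis and the hypoxia response and of growth-factor feedback were slightly lower, with mean log2 changes of 0.11, -0.12 and -0.092. These 3 calls of limma's camera with a preset correlation were lost with an estimated correlation, at adjusted p = 0.44, 0.38 and 0.38. Reported targets of the miR-25 family were not higher as a group, with a mean change of -0.050. No single gene passed the threshold in either direction: limma called 0 of 18656 genes, and the smallest adjusted p was 0.79. At an unadjusted p under 0.05, 551 genes were higher and 590 lower, 1141 in all against 933 that chance would give. Only 72 genes had a mean difference of 1.5-fold or more and 12 of 2-fold or more. The 3 inhibitor arrays lay wholly above or below the 3 control arrays for 2403 genes (12.9%), where chance gives 10%. Correlations of gene values between arrays were 0.9914 to 0.9948 within groups and 0.9904 to 0.9944 between groups, so arrays of different groups were about as alike as replicates. Control replicate 1 stood furthest from the rest, with a mean correlation of 0.9915 to the other arrays against 0.9933 to 0.9938 for those.

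**Figure D1:**
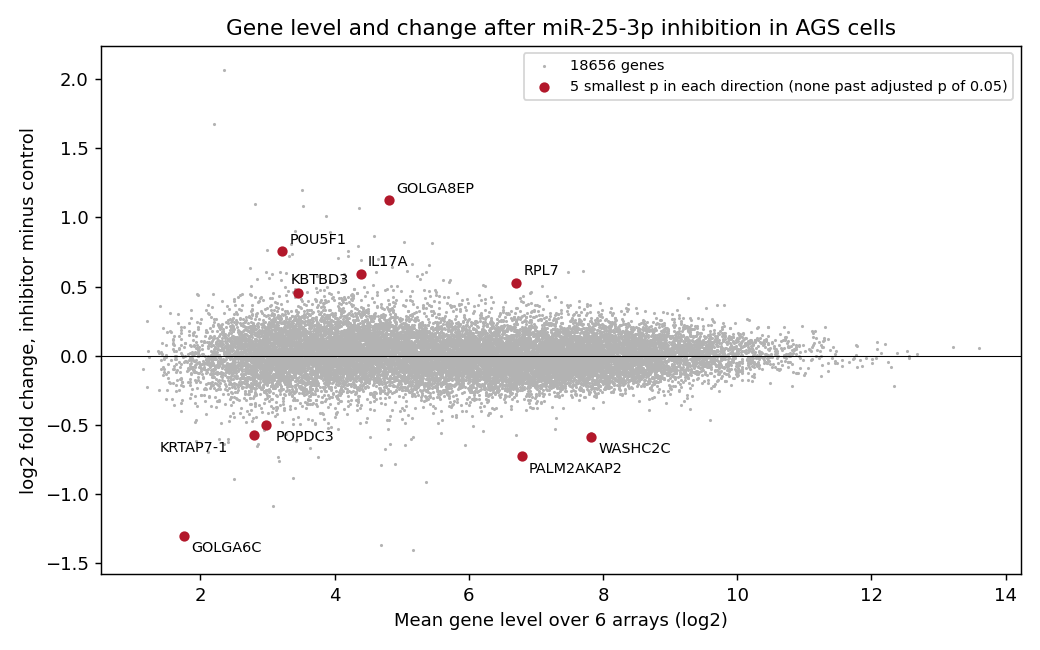
Log2 fold change (inhibitor minus control, vertical axis) against mean log2 level over 6 arrays (horizontal axis) for 18656 genes. Red points are the 5 genes with the smallest p in each direction, none of which passed an adjusted p of 0.05; the widest scatter lies among dim genes.

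The reported targets of the miR-25/92 family, which share a seed sequence, were not called higher. Of 33 measured members, 12 had a positive and 21 a negative fold change, and 0 passed the threshold, whether adjusted over all genes or adjusted over the list alone. The list mean was 6.99 ± 0.0077 (SD, n = 3) in control and 6.94 ± 0.010 (SD, n = 3) in inhibitor arrays, a mean change of -0.050, and all inhibitor arrays lay below all control arrays, an order that an exact test of 3 against 3 arrays cannot put below p = 0.1. Camera gave an adjusted p of 0.19 for this list (adjusted p = 0.38 with an estimated correlation), in a range of 0.19 to 0.91 over camera's alternatives. Fry, which does not compare a list with other genes, gave an adjusted p of 0.066 for a downward shift. The mean change was -0.033 with the brightest probe set of each gene and -0.080 without the dimmest 30% of probe sets. The most positive evidence was for MOAP1, a modulator of apoptosis, at 0.18 (SE 0.088), but it turned to -0.022 with the median of its probe sets. DSC2, a desmosomal cadherin, had 0.098 (SE 0.082), the MAP kinase phosphatase DUSP5 0.16 (SE 0.16) and EZH2, a histone methyltransferase, 0.079 (SE 0.084). The opposite side held SMAD7, an inhibitor of TGF-beta signalling, at -0.34 (SE 0.10, all 7 probe sets negative). It also held ITGA5, the fibronectin receptor subunit, at -0.25 (SE 0.092) and the transcription factors KLF4 at -0.22 (SE 0.10) and HAND2 at -0.26 (SE 0.13), the last with 5 of 7 probe sets positive and turning to 0.15 with its brightest. In simulated arrays with genes drawn independently, camera with the preset correlation called a rise of 0.1 in all 33 members in 88% of 50 runs. A rise of 0.05 was called in 8%. Camera with an estimated correlation was not run on simulated arrays.

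**Figure D2:**
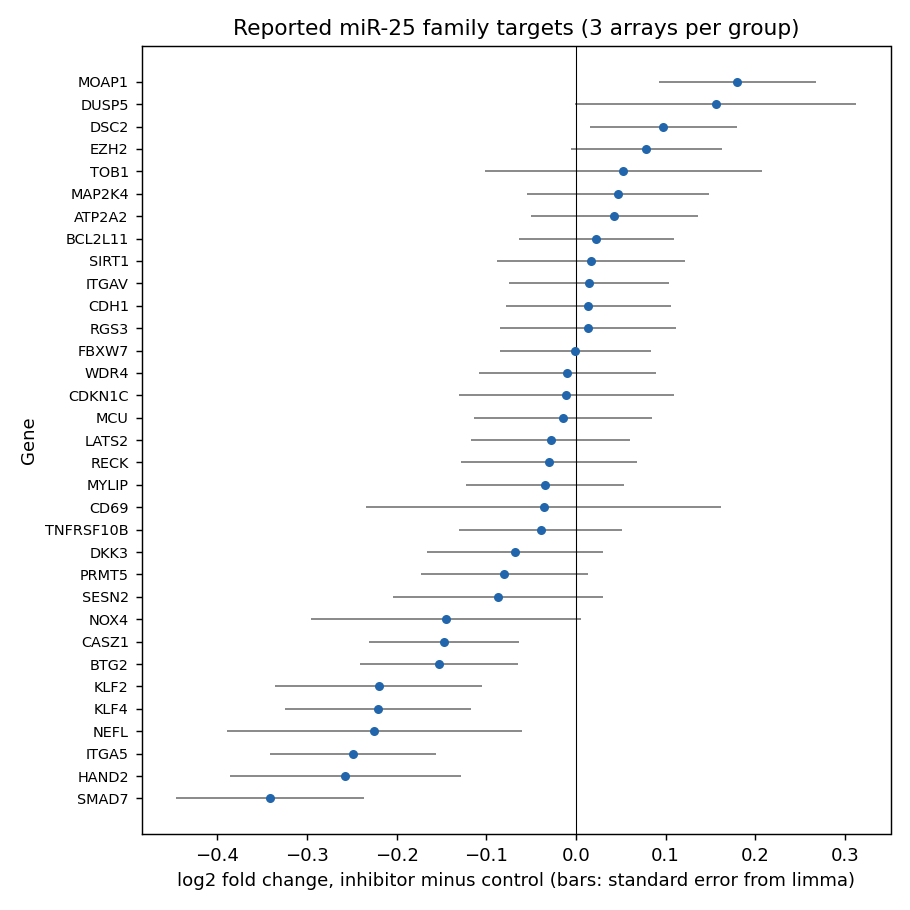
Log2 fold change (inhibitor minus control, horizontal axis) of the 33 measured reported targets of the miR-25 family, 1 gene per row. Points are estimates and bars standard errors from limma; 12 lie above 0 and 21 below, and none passed the threshold.

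Genes of the G2/M phase and mitosis were higher as a list in the inhibitor arrays. Of 29 members, 27 had a positive fold change, with a mean of 0.11, and the list mean went from 8.93 ± 0.082 (SD, n = 3) to 9.04 ± 0.033 (SD, n = 3). Camera with the preset correlation called the list, at an adjusted p of 0.0012, but the call was lost with an estimated correlation (adjusted p = 0.44). The mitosis members varied together between replicates, although the feedback list, whose estimate was -0.025, lost its call too. The members with the strongest evidence were CENPE, a kinetochore motor, at 0.33 (SE 0.13, 45 of 50 probe sets positive) and HMMR, a spindle-associated hyaluronan receptor, at 0.32 (SE 0.12), which turned to -0.053 with the median of its 19 probe sets. The 2 members with negative estimates were the mitotic kinase PLK1 at -0.047 (SE 0.11) and the ubiquitin-conjugating enzyme UBE2C at -0.026 (SE 0.094). With the median of probe sets these became 0.043 and 0.24. No member passed the threshold, adjusted over all genes or adjusted over the list alone. Without control replicate 1 the mean shift was 0.064 and the adjusted p 0.071, and with only the brightest probe set of each gene the shift was 0.0048 and the adjusted p 0.94, in a range of 0.00013 to 0.94 over camera's alternatives. Genes of the G1/S transition and DNA replication did not pass, with a mean change of 0.048 over 30 members and an adjusted p of 0.25.

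Genes of glycolysis and the hypoxia response were lower as a list, with 21 of 27 members negative and a mean change of -0.12. The list mean went from 8.45 ± 0.054 (SD, n = 3) to 8.34 ± 0.064 (SD, n = 3), although 1 inhibitor array overlapped the controls. Camera with the preset correlation gave an adjusted p of 0.0020, and the call was lost with an estimated correlation (adjusted p = 0.38). PFKFB3, which makes the allosteric activator of phosphofructokinase, had -0.24 (SE 0.084, 18 of 21 probe sets negative) and the glycolytic enzyme PGAM1 -0.32 (SE 0.12, all 4 probe sets negative). On the other side, ENO2, the neuronal enolase, had 0.034 (SE 0.084), turning to -0.0055 with quantile normalization, and GAPDH 0.031 (SE 0.088), turning negative with its brightest probe set. No member passed the threshold, adjusted over all genes or adjusted over the list alone. Without control replicate 1 the mean shift was -0.090 and the adjusted p 0.071, and with the brightest probe sets alone the mean shift was -0.11 and the adjusted p 0.21, in a range of 0.00029 to 0.38 over camera's alternatives.

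Growth-factor feedback and immediate-early genes, which follow MAP kinase activity, were lower as a list, with 19 of 25 members negative and a mean change of -0.092. The list mean was 7.10 ± 0.025 (SD, n = 3) in control and 7.01 ± 0.011 (SD, n = 3) in inhibitor arrays, with no overlap of arrays. The uncalled lists of reported targets and of gastric lineage genes had no overlap of arrays either. For the feedback list, camera with the preset correlation gave an adjusted p of 0.014. With an estimated correlation the call was lost (unadjusted p = 0.023, adjusted p = 0.38). That estimate was -0.025, below the preset 0.01, so members varying together does not account for this loss. With an estimated correlation camera rests on fewer degrees of freedom, which raises p without any correlation. SPRY2, a feedback inhibitor of receptor tyrosine kinase signalling, had -0.57 (SE 0.16, all 4 probe sets negative) and the AP-1 subunit JUN -0.20 (SE 0.087, all 5 probe sets negative). DUSP5 had 0.16 (SE 0.16) and SPRY1 0.052 (SE 0.11), the latter turning to -0.029 with array weights and to -0.046 without control replicate 1. No member passed the threshold, adjusted over all genes or adjusted over the list alone. The list call also ended when the median of probe sets was used (mean change -0.031, adjusted p 0.50) and when control replicate 1 (0.071), control replicate 2 (0.059) or inhibitor replicate 3 (0.053) was left out, in a range of adjusted p from 0.0057 to 0.50 over camera's alternatives.

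**Figure D3:**
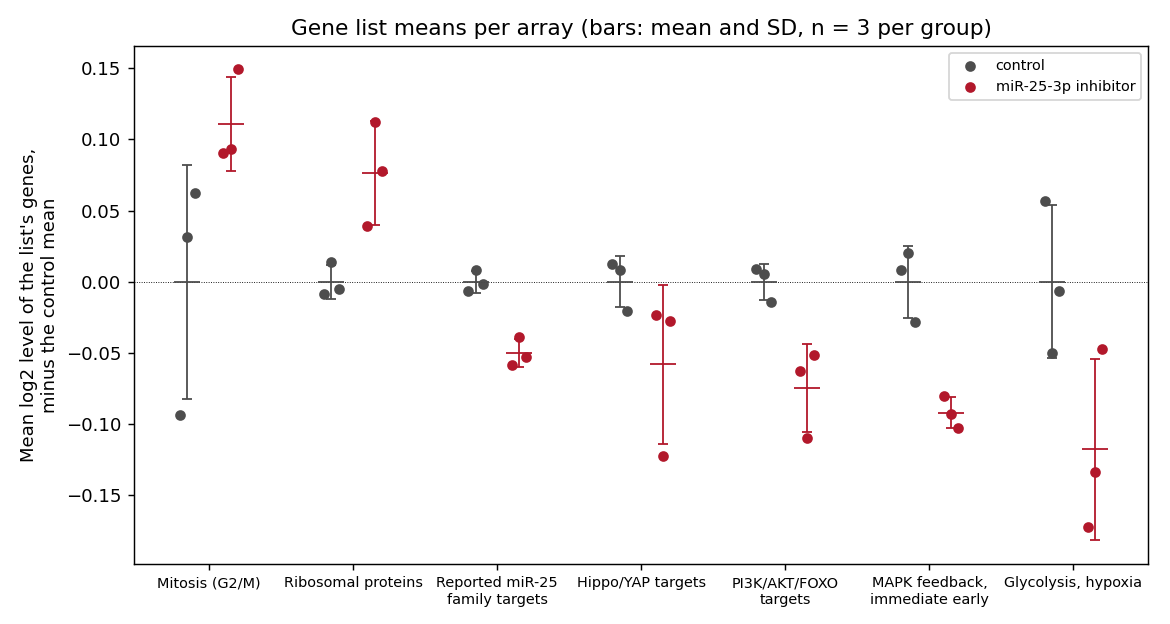
Mean log2 level of the genes of 7 lists on each array, minus the control mean (vertical axis), for control arrays (grey) and inhibitor arrays (red). Points are arrays and bars the mean and SD (n = 3); the shifts run from 0.11 for mitosis to -0.12 for glycolysis and hypoxia, and 1 glycolysis and hypoxia point of the inhibitor group overlaps the controls.

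Another 3 lists had an adjusted p of 0.051 with the preset correlation, and each an adjusted p of 0.38 with an estimated correlation. Cytosolic ribosomal protein genes had a mean change of 0.076, with 24 of 36 members positive. RPL7 had 0.53 (SE 0.10), the only member past the threshold when adjusted over the list alone (adjusted p 0.015 in limma), and RPL15 had 0.31 (SE 0.12), while RPS4X had -0.14 (SE 0.11) and RPL6 -0.088 (SE 0.082), the last turning positive with the median of its probe sets. Ribosomal protein genes have many processed pseudogenes, so their probe sets may read more than 1 locus. Targets of the Hippo effector YAP had a mean change of -0.058, with 16 of 19 negative. Among them the matricellular protein gene CCN1 had -0.34 (SE 0.11) and F3, which encodes tissue factor, -0.25 (SE 0.096), while NT5E had 0.17 (SE 0.11) and FJX1 0.72 (SE 0.33) on 2 discordant probe sets, -0.013 on the brighter. Targets downstream of PI3K, AKT and FOXO had a mean change of -0.075, with 15 of 21 negative. The list was not split by the direction in which the pathway moves each gene. Its mean therefore gives no direction of pathway activity. CCND1, at -0.20 (SE 0.094), was also a member of the feedback and WNT lists, so these lists are not separate evidence. The transcriptional repressor BCL6 had -0.30 (SE 0.10, all 10 probe sets negative) and the mitochondrial kinase PINK1 -0.21 (SE 0.090), against IRS1 at 0.10 (SE 0.087) and FBXO32 at 0.11 (SE 0.10). The signs of PINK1 and FBXO32 turned with the brightest probe set and that of IRS1 with the median. The YAP and PI3K lists had 0 members past the threshold, adjusted over all genes or adjusted over the list alone. All 3 lists passed with the preset correlation when the dimmest 30% of genes were left out (adjusted p = 0.38 each with an estimated correlation and all genes).

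The other 27 lists did not pass. Targets of WNT and of TGF-beta signalling each had an adjusted p of 0.066, with mean changes of -0.065 and -0.074; the WNT list passed without the dimmest 30% of genes, and both passed without the dimmest 30% of probe sets, with the preset correlation. With an estimated correlation and all genes, both had adjusted p = 0.38. Gastric lineage genes had a mean change of -0.066 and oxidative phosphorylation genes of 0.054, both with an adjusted p of 0.16. Adjusted p was 0.17 for mesenchymal genes, which passed without the dimmest 30% or 50% of genes with the preset correlation (adjusted p = 0.38 with an estimated correlation and all genes), 0.23 for NOTCH targets, 0.49 for apoptosis regulators, 0.55 for cholesterol synthesis, 0.61 for intestinal lineage genes and 0.67 for MYC-driven ribosome biogenesis. It was 0.70 for heat shock, for epithelial junction genes and for interferon-response genes, which differed by -0.0083 on average. For replication-dependent histones it was 0.77, and 0.79 for fatty acid synthesis, NF-kB inflammatory genes and p53 targets. For the unfolded protein response it was 0.90, for metallothioneins and NRF2 targets 0.92, for autophagy and lysosome genes 0.97 and for the microRNA machinery 1.00. Markers of other cell types were dim on average, with list means of 4.09 in control and 4.13 in inhibitor arrays for fibroblasts, 4.73 and 4.75 for leukocytes, 4.13 and 4.05 for endothelium and 4.22 and 4.24 for erythroid and hepatic cells. The adjusted p values of these lists were 0.69, 0.85, 0.55 and 0.90. Single markers could be brighter, such as the hepatic marker FGB at 7.04 in control and 7.22 in inhibitor arrays. The mean and the median differed in sign for leukocyte markers (0.023 and -0.0089), metallothioneins (0.0046 and -0.022) and NRF2 targets (0.012 and -0.0053), and camera's direction was downward for the last pair of lists.

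The 10 single genes with the smallest p, 5 in each direction, had no overlap of arrays between groups, and each had an adjusted p of 0.79 in limma. On the positive side, POU5F1, a pluripotency transcription factor, went from 2.84 ± 0.065 to 3.60 ± 0.23 (SD, n = 3 each), a difference of 0.76 (SE 0.12). GOLGA8EP, a golgin pseudogene, had 1.12 (SE 0.20) on 1 probe set, RPL7 0.53 (SE 0.096), the cytokine gene IL17A 0.59 (SE 0.12) and KBTBD3 0.45 (SE 0.090). On the negative side, PALM2AKAP2, whose product anchors protein kinase A, went from 7.15 ± 0.046 to 6.43 ± 0.20 (SD, n = 3 each), a difference of -0.73 (SE 0.11) on 3 of 3 probe sets. GOLGA6C had -1.30 (SE 0.22) on 1 probe set, WASHC2C, a subunit of the endosomal WASH complex, -0.59 (SE 0.11), the keratin-associated protein gene KRTAP7-1 -0.58 (SE 0.11) and POPDC3 -0.50 (SE 0.098, 4 of 6 probe sets negative). WASHC2C turned to 0.093 with its brightest probe set. POU5F1, RPL7, WASHC2C and the golgin genes have near-identical copies elsewhere in the genome, so their values are uncertain. In control arrays POU5F1 (2.84), GOLGA8EP (4.25), IL17A (4.09), KBTBD3 (3.22), GOLGA6C (2.40), KRTAP7-1 (3.08) and POPDC3 (3.23) lay below the array medians of 6.02 to 6.07.

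At the level of single probe sets, limma called 0 of 224320, with 13921 (6.21%) at an unadjusted p under 0.05 and a smallest adjusted p of 0.70. The 33110 probe sets that name several genes or none also gave 0 calls, with 1980 at an unadjusted p under 0.05.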

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

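Array weights, the restriction by probe set identifier and all settings of the KLF genes were chosen only after the results were seen. Under each alternative fit, limma called 0 genes in either direction, with 2 exceptions. Leaving out arrays gave 0 to 1 higher genes, the 1 being RGPD4 without control replicate 3, and a rule of unadjusted p under 0.05 with a 2-fold change gave 7 higher and 3 lower genes. Single probe sets gave 0 calls under each setting run on them, and genes at an unadjusted p under 0.05 ranged from 814 to 1688 over the settings and from 856 to 1271 when 1 array was left out. The lowest count, 814, was among the 9328 genes left without the dimmest 50%, a larger share than the 1141 of 18656 in the main fit. The replicate block gave 0 genes, 1161 at an unadjusted p under 0.05 and the same 3 list calls (adjusted p 0.0013 for mitosis, 0.0026 for glycolysis and hypoxia and 0.024 for MAPK feedback), so it changed no call. Deviations of same-numbered arrays from their group means had correlations across genes of -0.032, -0.040 and 0.17, and control replicate 1 correlated best with inhibitor replicate 2 (0.21), so the numbers were not taken to pair the arrays. The count of called lists, 3, became 8 and 6 without the dimmest 30% and 50% of genes, 7 without the dimmest 30% of probe sets, 1 with the brightest probe sets, 0 with an estimated correlation, 0 with fry's test for a shift in 1 direction and 0 to 7 when 1 array was left out, 0 without control replicate 1 and 7 without inhibitor replicate 1. Fry's test for change in either direction passed for Hippo/YAP targets (adjusted p 0.014), ribosomal proteins (0.034), WNT targets (0.034) and PI3K, AKT and FOXO targets (0.038). The cause was not tested beyond the values given here. For mitosis, adjusted p was 0.94 with the brightest probe set, 0.44 with an estimated correlation, 0.29 with fry and 0.000340 to 0.071 leaving out arrays. For glycolysis and hypoxia these were 0.21, 0.38, 0.18 and 0.000293 to 0.071. For MAPK feedback, adjusted p was 0.50 with the median of probe sets, 0.38 with an estimated correlation, 0.059 with fry and 0.021 to 0.071 leaving out arrays. No list reversed among those given a direction. Among named genes, the sign turned with the median of probe sets for HMMR (-0.053), PLK1 (0.043), UBE2C (0.24), IRS1 (-0.10), RPL6 (0.090), MOAP1 (-0.022) and MCM7 (-0.010). With the brightest probe set it turned for WASHC2C (0.093), UBE2C (0.023), FBXO32 (-0.093), PINK1 (0.13), GAPDH (-0.07), FJX1 (-0.013), HAND2 (0.15) and MCM7 (-0.010). FJX1 turned without the dimmest probe sets (-0.013), ENO2 with quantile normalization (-0.0055) and SPRY1 with array weights (-0.029). Leaving out arrays gave SPRY1 -0.046 to 0.13, PLK1 -0.11 to 0.030, UBE2C -0.065 to 0.043 and GAPDH -0.014 to 0.068. The planned seed-site test and its alternatives were not run. An unadjusted p under 0.05 was found for 6.94% of genes under a mean level of 4 and 3.19% of those over 9.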

Other observations

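The grouping of genes by symbol, the splits for genes and lists, and the tests of control replicate 1, of correlation between list members, of the brightest probe sets and of the way probe sets are combined were chosen only after the result was seen. Genes were grouped by the leading letters of their symbols, which gave 142 families of at least 15 genes. Krüppel-like transcription factors were the family with the smallest p: 16 of 17 KLF genes had a negative fold change, with a mean of -0.15, and the family mean went from 6.51 ± 0.062 to 6.36 ± 0.026 (SD, n = 3 each) with no overlap of arrays. With the brightest probe set of each gene 35.5% of this shift was kept, and without the dimmest 30% of probe sets 45.9%. The RPL and MYO families, which camera did not call, had no overlap of arrays either. For the KLF genes the results were as follows. Camera with the preset correlation gave an adjusted p of 0.0048 over the families, and 0 members passed the threshold on their own. Camera with an estimated correlation gave an unadjusted p of 0.011 and an adjusted p of 0.99 over the 142 families. The estimate was -0.0036, so members varying together does not account for the lost call. The fewer degrees of freedom of that test apply here too. KLF13 had -0.28 (SE 0.14), KLF6 -0.18 (SE 0.093), KLF2 -0.22 (SE 0.12) and KLF14, a dim gene, -0.52 (SE 0.19), named here after their values were seen. The 13 members outside the fixed lists had a mean of -0.15. No other family passed camera, and the KLF genes did not pass fry (adjusted p 0.30 for a shift in 1 direction and 0.30 for change in either direction). Fry's test for change in either direction, which does not compare a family with other genes, passed for the MYO, POU and DNAJC stems (adjusted p 0.013 each) and the MED and CDK stems (0.036 each). The RPL stem (43 of 64 positive), used for large-subunit ribosomal protein genes and not checked for pseudogenes, had an adjusted p of 0.22 in camera. For H/ACA small nucleolar RNAs (SNORA stem, 41 of 60 positive) it was 0.38.

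The 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. Counts out of these 10 include the real split itself. The real split gave 1141 genes at an unadjusted p under 0.05 and 3 of the 10 splits gave as many, the highest other split giving 1496. It gave 3 called lists, 2 of the 10 splits gave as many, and the highest other split also gave 3, namely histones, interferon response and oxidative phosphorylation. The mitosis list was also called in 1 other split and the glycolysis and hypoxia list in 1 other. It gave 13921 probe sets at an unadjusted p under 0.05, which 2 of the 10 splits reached, the highest other split giving 14835.

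The first pattern is the higher mitosis list together with the lower glycolysis and hypoxia list. Members of the lists varied together within groups, with estimated inter-gene correlations of 0.22 and 0.13. This makes replicate-to-replicate variation of the cultures a candidate explanation for both calls. Neither list was called with an estimated correlation, but the feedback list and the KLF genes, with estimates of -0.025 and -0.0036, lost their calls too. The lost calls alone therefore do not show that such variation made the calls. Control replicate 1 had the lowest mitosis mean and the highest glycolysis mean. Without it the lists kept 57.9% and 76.1% of their shifts and lost their calls. With array weights, which gave this array 0.45, camera with the preset correlation still called both (adjusted p 0.020 each). Their mean shifts were then 0.085 and -0.10. How far the calls depend on this 1 array stays open. With the brightest probe set of each gene alone, the mitosis list kept 4.35% of its shift, so a shift carried by the less bright probe sets of each gene is a candidate explanation, although the list kept 114% with the median and 90.8% without the dimmest probe sets, and the mean change was 0.27 for probe sets under a level of 7, 0.11 for the 258 at 9 to 11 and 0.047 over 11. The glycolysis list kept 96.3%, which argues against that explanation for it, and an effect of the inhibitor, the difference the design names, stays open.

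The second pattern is that reported miR-25 family targets were not higher. Dim probe sets hiding a rise is argued against by a mean change of -0.080 without the dimmest 30% of them, -0.033 with the brightest and -0.039 with the median probe set, and control replicate 1 by -0.054 without it. Scaling stays open: the value nearest to 0 under median centring and quantile normalization was -0.044, but on values already normalized with RMA these moved the list by less than the SD of its control means. Whether the inhibitor bound the microRNA, whether these genes are repressed by it in AGS cells, and whether an effect falls on protein rather than message stay open; a seed-site test would bear on the first pair and was not run.

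The third pattern is the lower level of growth-factor feedback and KLF genes. Leaving out control replicate 1 kept 95.6% of the shift of the feedback list and 77.5% of that of the KLF genes. That array alone therefore does not account for these shifts. The feedback list lost its camera call without it (adjusted p 0.071) but kept the call with array weights (adjusted p 0.020). How far that call depends on this array stays open. Scaling stays open, since median centring and quantile normalization kept at least 92.9% but moved both groups by less than the SD of their control means. The way probe sets are combined remains a candidate explanation for the size of each shift, but no single way removed both: the feedback list kept 33.5% with the median, 140% with the brightest probe set and 88.6% without the dimmest probe sets, and the KLF genes kept 105%, 35.5% and 45.9%. GC content was not tested, because no sequences were used here, and an effect of the inhibitor stays open as a hypothesis.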
